A study of Mus musculus with 30 samples.

How the data were processed

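Integration sites of therapeutic transposons were mapped in genomic DNA from 30 livers of Fah knockout mice, a model of tyrosinemia type I (TT1). The labels put 17 livers in a piggyBac (PB) group and 13 in a Sleeping Beauty (SB) group. Per the labels' protocols, the DNA was fragmented enzymatically, ligated to a linker, size-selected and amplified in nested PCRs with a biotinylated transposon-specific primer before Illumina sequencing, an assay called streptavidin-based enrichment sequencing (SBE-seq). Cutadapt, BWA and the mouse build GRCm39 are named in the submitters' processing notes, without versions.

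The deposited table of each liver lists sites with their chromosome, position, strand and a whole number. What that number is was not given in the sources used here. It was taken as the reads behind a site and is called its support. Its smallest value in either group was 3, so sites with less support are not seen here. PB sites span 4 bp and SB sites 2 bp. A pair of deposited merged tables, covering livers 1 to 12 of each group, matched the number of liver and strand records at all 833852 PB and all 925116 SB positions and was not used further. Amplified reads without molecular identifiers are not independent molecules, so support is not a count of cells.

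The gene table at hand describes GRCm38.p6 and no genome sequence was used, so positions were not assigned to genes, exons, promoters, CpG islands, repeats or target motifs. The planned comparisons that needed them are not analysed here. As a substitute chosen after the data were examined, nuclear sites were counted in windows of 1 Mb, and windows with a mean of at least 1 site per liver were tested with limma 3.58.1 in R 4.3.3 (voom weights, total sites per liver as library size, Benjamini-Hochberg adjusted p under 0.05). The rule for genes to be named, fixed before the data were examined, was applied to windows. It takes the 10 windows with the largest difference in each direction, the 5 densest in each group and the 3 positions found in most livers of each group.

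Other measures were computed per liver with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A site was shared when its exact position and strand occurred in another liver of its group. The effective target number is the product of the site numbers of a pair of livers divided by their coincidences, summed over partners. It equals the number of equally used position and strand targets that would give the observed coincidences. Regional concentration is the extra-Poisson coefficient of variation (CV) of autosomal site counts over windows. Groups were compared by two-sided permutation tests of the difference of means with 100000 resamples (exact where 5 livers were set against 12), on log2 values for numbers, shares and the effective target number. The smallest p these resamples can give is printed as 1e-05. The shared share and the effective target number of a liver are computed against the other livers of its group. Their values within a group therefore depend on each other. The permutation tests moved the finished values without recomputing them, so for these measures they are not tests over independent livers. A family of 12 group measures was adjusted together by the Benjamini-Hochberg method, and 20 chromosomes formed another family.

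The window test was tested on simulated counts with the real window means and liver totals and a spread between livers of 5.38%, estimated from the data. Over 20 simulations with 200 changed windows each, 88.6% of windows changed 1.5-fold were recovered on average (range 83.6% to 97.0%). At 1.3-fold the average was 61.9% (43.3% to 76.1%) and at 2-fold 98.1% (95.5% to 100%). Between 0 and 11 unchanged windows were called per simulation. The simulated changes went up and down in equal numbers. The real median window lay at -0.16 on the log2 scale (PB minus SB), and the simulated false calls do not cover such a shift. The effective target estimate came to 1.00 times the true value in simulated PB livers and 0.991 times in simulated SB livers. These simulated livers drew from pools of equally used targets, of size 2 for PB and 40 for SB in units of 1000000. The simulation therefore checks the calculation only. It does not cover uneven use of positions, as found in the real livers.

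Alternatives covered livers 1 to 12 alone, the liver number as a block, merging of sites within 10 bp, leaving out positions found in more than 1 liver, thinning every liver to 4893 sites, a support minimum of 10, leaving out SB liver 13, and other window filters, sizes, tests and scalings. Leaving out positions found in more than 1 liver removes far more PB than SB sites. With strand ignored, 38.0% of a PB liver's positions and 3.89% of an SB liver's were shared on average. Results of that alternative therefore do not compare the groups on like terms. Each liver was treated as 1 replicate. The labels do not describe how livers numbered 13 and above differ from the others.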

Results

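Insertion sites of PB and SB gene therapy vectors were compared in livers of Fah knockout mice. These mice lack fumarylacetoacetate hydrolase, the last enzyme of tyrosine breakdown. PB and SB are DNA transposons whose transposases insert at TTAA and TA target sites. The 17 PB livers held 1232298 site records and the 13 SB livers 949436. PB liver site numbers ran from 16364 to 124238, and SB liver site numbers from 4893 to 120220.

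The size of the site catalogue was compared between the vector systems first. PB livers held 72488 ± 36601 sites (SD, n = 17) and SB livers 73034 ± 30164 (SD, n = 13), a difference smaller than the spread between livers (permutation test, p = 1). Livers numbered 1 to 12 held 92248 ± 21547 PB sites and 78712 ± 23136 SB sites (SD, n = 12 each), which also did not pass the permutation test (p = 0.15). Within PB, livers 13 to 17 held 25064 ± 9953 sites (SD, n = 5), 3.81-fold fewer than livers 1 to 12 (exact permutation test, p = 0.00016, adjusted p = 0.00064 over 8 measures). The median support of a site was 108.8 ± 38.2 in PB livers 13 to 17 and 54.3 ± 22.5 in PB livers 1 to 12 (exact permutation test, adjusted p = 0.013). In the same order, the effective target number was 1625290 and 1795690 (exact permutation test, adjusted p = 0.0013). Regional concentration over 1 Mb was 0.673 and 0.648 (exact permutation test, adjusted p = 0.008). Shannon evenness of support was 0.983 and 0.986 (exact permutation test, adjusted p = 0.032). The X share did not pass (exact permutation test, adjusted p = 0.084). SB liver 13, the single SB liver above 12, held 4893 sites.

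**Figure D1:**
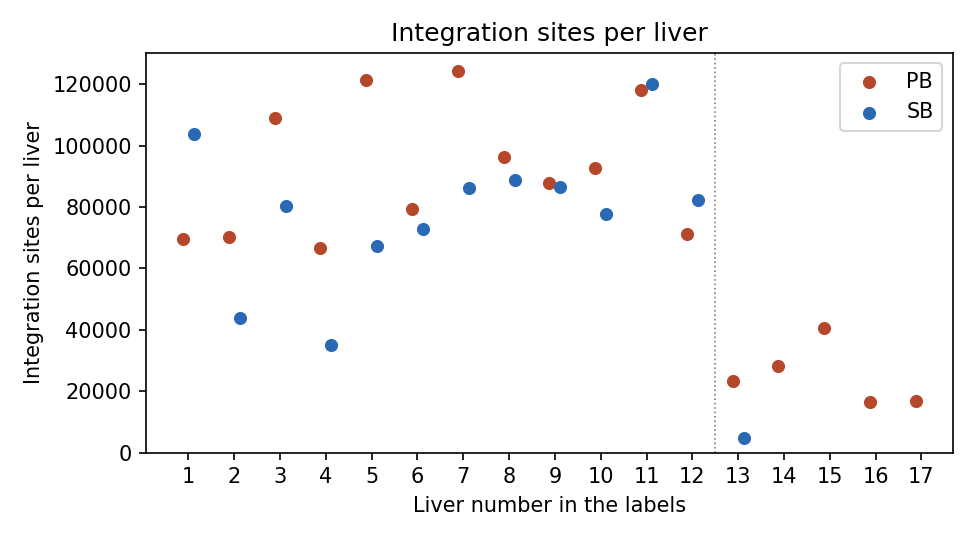
Integration sites per liver (y axis, number of sites) against the liver number in the labels (x axis), with 1 point per liver and a dotted line after liver 12. PB livers 13 to 17 lie between 16364 and 40598 sites and SB liver 13 at 4893.

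Reuse of the same genomic positions was then compared between livers. In PB livers, 29.3% ± 1.4 of sites (SD, n = 17) lay at a position and strand also hit in another PB liver, against 2.13% ± 0.15 in SB livers (SD, n = 13). The ratio was 13.7-fold on the log2 scale (permutation test, p = 1e-05, the smallest 100000 resamples can give, adjusted p = 2e-05). The effective target number was 1745570 ± 96577 in PB and 37073800 ± 2763660 in SB, 21.2-fold higher in SB (permutation test, p = 1e-05). Every coincidence counts in both livers of a pair, so the p-values of the shared share and the effective target number do not rest on independent livers. Of 908736 PB positions, 153971 (16.9%) occurred in at least 2 livers and 1611 in at least 10. Of 929804 SB positions, 17780 (1.91%) occurred in at least 2 livers and none in 10 or more.

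**Figure D2:**
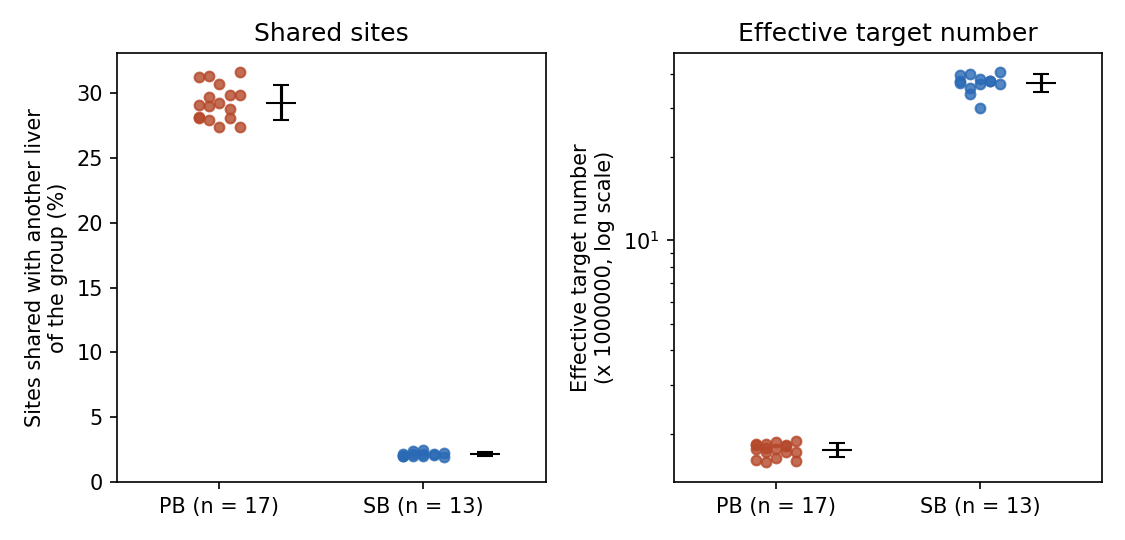
Left, share of a liver's sites found at the same position and strand in another liver of its group (%). Right, effective target number on a log axis, in units of 1000000. Points are livers and bars the mean ± SD; all 17 PB livers lie above all 13 SB livers on the left and below them on the right.

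The PB positions found in most livers were on chromosome 15 from 10378786 to 10378789, on chromosome 11 from 3096764 to 3096767 and on chromosome 8 from 15834144 to 15834147 (GRCm39), each in 17 of 17 livers. The chromosome 15 position carried 14 plus-strand and 14 minus-strand records, whereas all 17 records of the chromosome 8 position were on the minus strand. The SB positions found in most livers were on chromosome 10 from 5537492 to 5537493 and on chromosome 17 from 83296315 to 83296316, each in 9 of 13 livers and each on a single strand. A further 5 positions were found in 8 of 13 livers. Of these, the position on chromosome 11 from 3091320 to 3091321 had the most records, 9, on both strands, while the other 4, among them chromosome 3 from 80986951 to 80986952 and from 83970636 to 83970637, had 8 records each on a single strand. At the chromosome 17 position the median support was 8.

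PB sites were also more unevenly spread along the chromosomes. Over 1 Mb windows the extra-Poisson CV of site density was 0.655 ± 0.019 in PB (SD, n = 17) and 0.455 ± 0.042 in SB (SD, n = 13). Over 100 kb windows it was 1.11 ± 0.04 and 0.623 ± 0.105, and over 10 kb windows 1.76 ± 0.17 and 0.887 ± 0.471 (permutation tests, each p = 1e-05). SB liver 13 had the highest 10 kb value in SB, 2.42, and without it the 10 kb difference between PB and SB was 0.996 in place of 0.868. The densest 10% of 1 Mb windows, ranked on the same livers, held 23.1% ± 0.5 of autosomal PB sites and 17.9% ± 1.0 of SB sites. Without positions found in more than 1 liver the 1 Mb difference in CV fell from 0.200 to 0.0583 (permutation test, p = 1e-05). The 100 kb difference was then 0.220 in place of 0.491 (p = 1e-05), the 10 kb difference 0.444 in place of 0.868 (p = 0.006), and the gap in the share of the densest windows 1.66 in place of 5.17 percentage points (p = 1e-05).

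**Figure D3:**
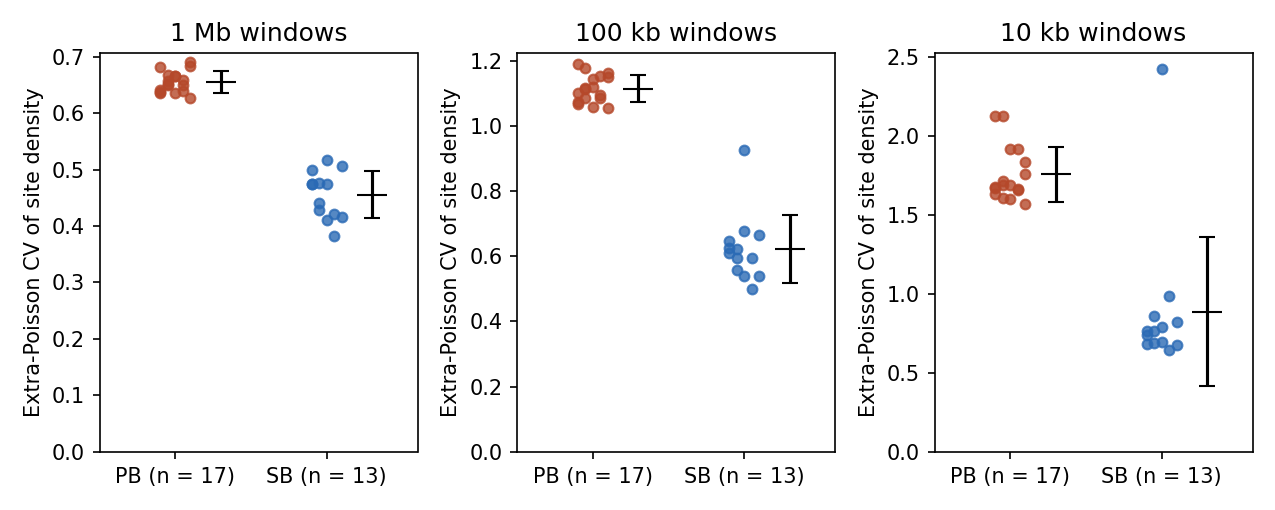
Extra-Poisson CV of autosomal site density (y axis) in windows of 1 Mb, 100 kb and 10 kb for each liver, with the mean ± SD beside the points. The 1 Mb values run from 0.626 to 0.691 in PB and from 0.382 to 0.516 in SB.

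Of 2578 windows of 1 Mb tested, 498 had a higher density in PB and 1003 in SB (limma-voom, adjusted p under 0.05). The median window lay at -0.16 on the log2 scale (PB minus SB), and relative to that median 807 windows were higher in PB and 598 in SB. Without positions found in more than 1 liver, a removal that takes far more PB than SB sites, the counts were 185 and 220. The largest PB excess was on chromosome 7 from 73 to 74 Mb, with 7.08 ± 1.43 sites per 10000 in PB and 2.62 ± 1.12 in SB (log2 difference 1.25, SE 0.12, limma adjusted p = 4.2e-13), and the difference was 0.56 without positions found in more than 1 liver. Chromosome 4 held 4 of the 10 windows with the largest PB excess, from 61, 82, 97 and 150 Mb. The others were on chromosomes 5, 8, 10, 14 and 16. The window on chromosome 5 from 87 to 88 Mb was the densest in PB, with 16.5 ± 1.7 sites per 10000 against 8.38 ± 2.14 in SB.

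The 10 windows with the largest SB excess held 0.341 to 2.80 sites per 10000 in SB. The first, on chromosome 14 from 110 to 111 Mb, held 1.76 ± 0.87 sites per 10000 in SB and 0.655 ± 0.301 in PB (log2 difference -1.25, SE 0.22, limma adjusted p = 4.4e-06). The others were 2 more windows of chromosome 14 (from 42 and 95 Mb), windows of chromosome 4 (from 68 and 127 Mb) and chromosome 1 (from 28 and 123 Mb), and single windows of chromosomes 3, 6 and 15. Without positions found in more than 1 liver, 6 of these 10 windows no longer passed the threshold, the chromosome 14 window from 110 Mb among them (log2 difference -0.61, limma adjusted p = 0.051). The densest SB window was on chromosome 11 from 3 to 4 Mb, with 14.6 ± 2.3 sites per 10000 in SB and 10.0 ± 1.6 in PB (log2 difference -0.55, SE 0.07, limma adjusted p = 7.8e-09). The recurrent chromosome 11 positions of PB and SB named above both lie in it. Whether the mice carry more copies of this window than GRCm39 was not examined. Among the other densest SB windows, those on chromosome 18 from 35 Mb, chromosome 5 from 145 Mb and chromosome 3 from 118 Mb had higher PB means. Of these only the chromosome 3 window passed, with 11.6 sites per 10000 in PB and 9.14 in SB (limma adjusted p = 6.3e-05). The window on chromosome 4 from 132 Mb was higher in SB, 9.21 against 8.02, without passing (limma adjusted p = 0.084).

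**Figure D4:**
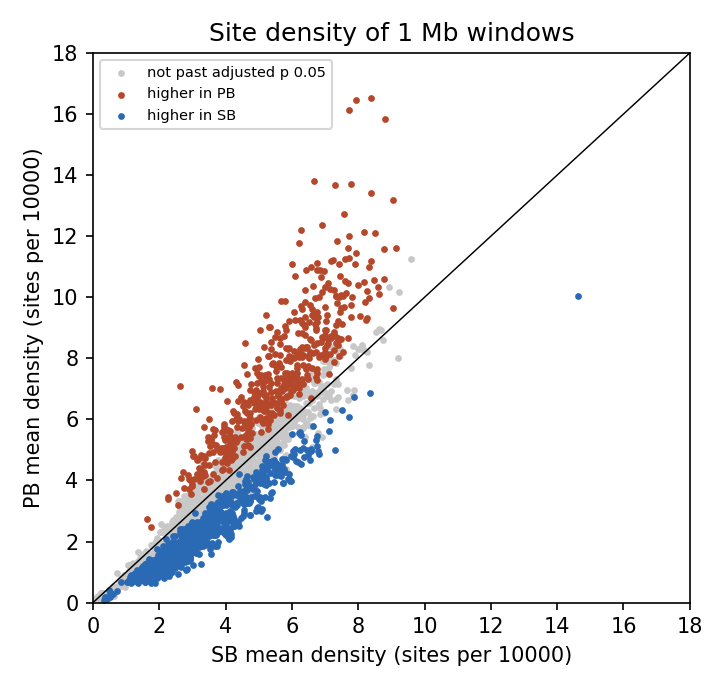
Mean site density of 2578 windows of 1 Mb in SB (x axis) and PB (y axis), in sites per 10000 sites of a liver, coloured by the limma-voom call. The line marks equal density; the densest SB window, on chromosome 11, lies at 14.6 in SB and 10.0 in PB.

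Among autosomes, 6 took a higher share of PB sites (chromosomes 3, 4, 6, 10, 13 and 19) and 6 a higher share of SB sites (chromosomes 1, 5, 7, 12, 15 and 17). Without positions found in more than 1 liver these numbers were 2 and 4. Chromosome 19 held 3.61% ± 0.07 of autosomal PB sites and 3.38% ± 0.13 of SB sites (permutation test, adjusted p = 0.0001). Chromosome 7 held 5.09% ± 0.19 of PB and 5.37% ± 0.11 of SB sites (permutation test, adjusted p = 0.00025). The X chromosome held 3.09% ± 0.65 of nuclear PB sites and 3.32% ± 0.84 of SB sites, which did not pass the test over all livers (permutation test, p = 0.48). With the liver number as a block the PB to SB ratio was 0.890 (exact sign-flip test, p = 0.00049), though the numbers were not taken to pair the livers. X shares fell into separate ranges by liver number in both groups. In livers 1 to 6 they ran from 2.20% to 2.27% in PB and from 2.26% to 2.59% in SB, and in livers 7 to 12 from 3.49% to 3.65% and from 3.80% to 4.23%. In livers 7 to 12 every SB share lay above every PB share, while in livers 1 to 6 the ranges overlapped. The test over all livers counts the gap between the ranges as spread, so its p does not show equal X shares. These ranges were seen in the X shares themselves, so no test within them is given. Without positions found in more than 1 liver the X ratio turned to 1.21 in favour of PB (p = 0.067).

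Support was spread over many sites in both systems. The 10 best supported sites took 0.128% ± 0.092 of all support in PB livers and 0.177% ± 0.370 in SB livers (permutation test, p = 0.53). SB liver 13, the smallest library, stood at 1.41%. Without it the PB share was 1.51-fold higher (permutation test, p = 0.046), while in livers 1 to 12 alone the ratio was 1.07 (p = 0.58). The 10 best supported sites took 0.251% ± 0.080 of support in PB livers 13 to 17 and 0.0771% ± 0.0182 in PB livers 1 to 12 (exact permutation test, adjusted p = 0.00064). The share of a fixed number of sites rises as a liver holds fewer sites. With every liver thinned to 4893 sites the shares were 0.829% ± 0.220 and 0.893% ± 0.109 (exact permutation test, p = 0.29), and the PB to SB ratio over all livers was 1.09 (permutation test, p = 0.2). Shannon evenness of support was 0.985 ± 0.003 in PB and 0.981 ± 0.007 in SB (permutation test, adjusted p = 0.0087). SB liver 13 stood at 0.960, and without it the difference was 0.0023 in place of 0.0041 (permutation test, p = 0.019). The minus strand held 51.0% ± 0.4 of PB sites and 51.3% ± 0.9 of SB sites (permutation test, p = 0.13).

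**Figure D5:**
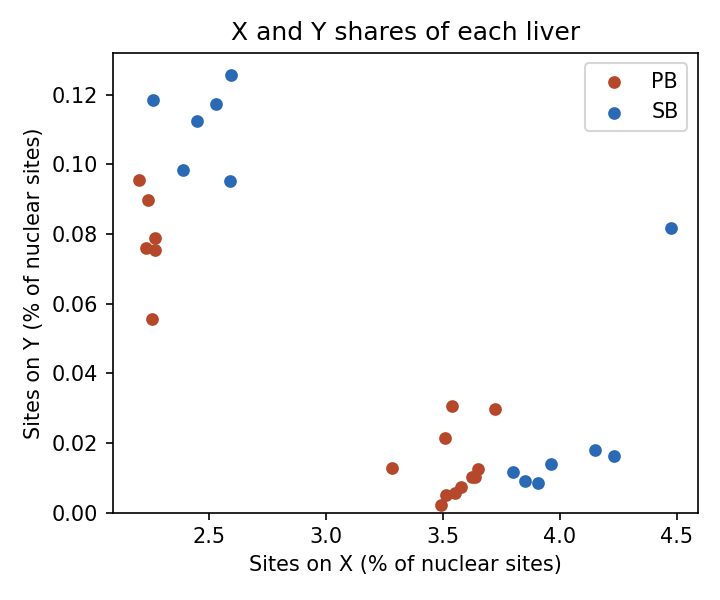
Share of nuclear sites on the Y chromosome (y axis, %) against the share on the X chromosome (x axis, %), with 1 point per liver. SB liver 13 lies apart at 4.48% on X and 0.0817% on Y.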

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

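The tests in this part were chosen after the result they bear on was seen, except thinning for shared positions, which was fixed before the data were examined. A total of 30 sites lay on the mitochondrial genome, 16 in PB and 14 in SB livers, in 17 of 30 livers, a signal outside the nuclear comparisons.

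PB livers shared far more positions than SB livers. Coincidences on opposite strands alone still gave a 24.7-fold higher effective target number in SB. Carry-over between libraries cannot make them from positions hit on 1 strand, so carry-over of such positions is argued against as the whole cause. Carry-over can make them where a library holds both strands, which occurred 30016 times within PB livers and 992 times within SB livers. Carry-over from these positions stays open. Depth is argued against as well, since the ratio of shared shares was 24.0 after thinning every liver to 4893 sites. The effective target number counts pairs of livers and so takes out the number of livers in a group. The number and evenness of TTAA and TA positions also stay open. They may account for the 21.2-fold difference and were not tested without a genome. Other explanations were not examined.

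The difference in CV between PB and SB over 1 Mb windows was 0.192 after thinning, against 0.200 before, which argues against depth. Without positions found in more than 1 liver it was 0.0583, so reused positions may carry much of the difference. That removal takes more sites from dense windows by construction, so it does not decide. The distribution of target motifs stays open for the whole difference of 0.200. The 1501 windows called between PB and SB exceeded those of the other splits. Of 100 splits, only the real one gave as many, which argues against a chance division of the livers. With 100 splits no share under 1 in 100 can be reached, so chance is not excluded. The window test was itself chosen after the data were examined. The highest of the others gave 28, with 13 of its 17 livers from PB. That highest value depends on the splits drawn: it was far higher in another draw, though below the real count.

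Of 37 SB positions found in at least 5 livers, 29 had every record on 1 strand, against 1.51 expected from random orientation. That is 19.2 times the expectation, which argues against independent insertions in either orientation. Their median support was 14, against 49.5 at positions with both strands. Spill-over of a well supported site from 1 library into others stays open, since 20.7% of these positions lay below the median support of every liver that held them. A sequence of the mouse genome that resembles the transposon end may also be amplified in many livers, which was not tested. In PB, 508 of 18516 positions found in at least 5 livers were on 1 strand, against 505.7 expected, but 36 against 9.64 in at least 8 livers and 6 against 0.0244 in at least 12.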

How the results depend on the processing

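Alternatives for sites per liver, the X share, shared positions and clonal dominance were fixed before the data were examined, except the support minimum, leaving out SB liver 13 and thinning for clonal dominance. All alternatives of the window, chromosome, CV and effective target results were added afterwards. Shared positions, the effective target number, CV and evenness kept their direction and their side of the threshold in every alternative run for them. The PB to SB ratio of sites per liver, 0.999, became 1.20 in livers 1 to 12 and 1.01 with a support minimum of 10. The X ratio became 1.21 without positions in more than 1 liver. Without SB liver 13 the ratio for the 10 best supported sites became 1.51 and for the best supported site 1.68. Thinning turned the ratio for the 10 best supported sites of PB livers 13 to 17 over PB livers 1 to 12 from 3.20 to 0.910. Leaving out positions in more than 1 liver gave 185 PB and 220 SB windows (14 and 43 at 1.5-fold or more) with 2 autosomes higher in PB and 4 in SB. Thinning, with fewer sites, gave 20 and 7 windows (20 and 7 at 1.5-fold or more) and 1 autosome each way. Windows of 100 kb gave 2157 and 3021 calls (2089 and 3020 at 1.5-fold or more). Limma-trend gave 101 SB windows at 1.5-fold or more, against 466. Centring on the median window gave 807 and 598 (179 and 215 at 1.5-fold or more). Log2 differences changed sign for chromosome 18 from 35 Mb (-0.0157) and chromosome 5 from 145 Mb (-0.0639) without positions in more than 1 liver, and when thinned for chromosome 5 from 145 Mb (-0.19) and chromosome 4 from 132 Mb (0.11). These 3 windows lay near the threshold: none passed it as reported, and each passed it in at least 1 alternative. The cause of the other changes was not tested.

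The liver numbers are shared by 13 pairs, but 1 of 13 pairs correlated above 0.1 over windows (range 0.02 to 0.14) and 1 liver correlated best with its own number, so the numbers were not taken to pair the livers. With the replicate block the ratio of sites per liver was 1.33 (exact p = 0.033), the X ratio 0.890 (exact p = 0.00049, SB higher in 12 of 13 pairs) and the ratio for the 10 best supported sites 0.961 (exact p = 0.82). For sites per liver and the X share the block changed the call. It left 4 of the 6 autosomes higher in SB, and no other group measure changed its call.

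Not run were all alternatives that need a genome or gene annotation of GRCm39, and leaving out sites with 1 read, since the smallest support was 3. Thinning to 4893 sites leaves few sites per window, which limits what it can show.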

Other observations

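The comparisons in this part were chosen after the data were seen. An SB position started 1 bp after a PB position in 2111 cases, against 506.6 ± 23.9 (SD over 100 offsets between 500 and 1000 bp), a ratio of 4.17. Every TTAA holds a TA at its centre, so an excess at this offset follows from the target sites. Distances between PB and SB positions from 160 to 179 bp were 1.05 times as frequent as the mean of the ranges from 100 to 119 and 220 to 239 bp (counting SE 0.01).

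X and Y shares fell into separate clusters that the labels do not describe. Livers 1 to 6 had X shares of 2.20% to 2.27% in PB and 2.26% to 2.59% in SB, with Y shares of 0.0556% to 0.0956% and 0.0952% to 0.126%. Livers 7 to 12 had X shares of 3.49% to 3.65% in PB and 3.80% to 4.23% in SB, with Y shares of 0.00216% to 0.0126% and 0.00851% to 0.0180%. PB livers 13 to 17 had X shares of 3.28% to 3.72% and Y shares of 0.00739% to 0.0306%. SB liver 13 had 4.48% on X and 0.0817% on Y, the latter from 4 sites. No group was formed from these values.

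Sites within 10 bp of a better supported site on the same strand made up 1.98% ± 0.47 of PB sites (SD, n = 17) and 1.95% ± 0.62 of SB sites (SD, n = 13). Their median support averaged 6.29 in PB and 5.15 in SB, against 71.2 and 56.1 for the sites kept. Despite the similar shares, the spacing of the recorded positions differed: pairs of sites 1 bp apart on the same strand numbered 19835 in PB livers and 724 in SB livers. Positions 1 bp apart cannot both start a TTAA or both start a TA. These pairs are therefore not read as a difference in insertion, and the sequence at them was not examined.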
